A study of Mus musculus with 6 samples.

How the data were processed

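The samples were C2C12 myotubes, a mouse myoblast line differentiated in low-serum medium, treated for 3 days with either a GL2 control siRNA, which is directed against firefly luciferase, or an siRNA against SENP7, a protease that removes SUMO from proteins. Polyadenylated RNA was sequenced in paired reads from 6 libraries, 3 per group, made with a directional kit and pooled in 1 run, per the labels' protocols. The submitters state that the 3 libraries of a group are biological replicates.

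Per the submitters' processing notes, the tools were bcl2fastq, Trim Galore 0.6.4, STAR 2.6.1d, featureCounts 1.6.4 and DESeq2, with the mouse genome build GRCm38.p6. The strand setting of the counting, the annotation release and the DESeq2 version are not given in the sources used here. The deposited table held 55401 genes. Its 6 library columns held a normalized signal, which from the values themselves was the authors' read count per gene divided by 1 factor per library, and the mean over the 6 libraries stood beside it. The table also held the authors' log2 fold change of SENP7 siRNA over control siRNA with its standard error, per the file headers. A Wald score for each gene was deposited too, as was its p-value with the adjusted value for the 27493 genes with a read. The authors' fold changes looked shrunken towards 0, since genes with a single read had small ones. All 54349 gene identifiers shared with GENCODE M21 had the same coordinates there. Of 987 blank gene names, 727 were filled from that release.

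In every library 100% of the positive values were whole multiples of 1 step, within 0.1 read, so that the reads could be recovered. The recovered totals were 27672491, 25223218 and 27763538 reads in control replicates 1, 2 and 3 and 30865945, 25434880 and 28488660 in SENP7 replicates 1, 2 and 3. A gene's precision follows from its reads, and a normalized count of 1 corresponds to about 1 read.

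The design named edgeR as the test for raw counts and limma-trend for normalized values. Because the table held normalized values, limma 3.58.1 (R 4.3.3) was fitted with robust empirical Bayes and a mean-variance trend on log2(normalized count + 1), for genes with a normalized count of at least 10 in at least 3 libraries, with the group as the sole term. Fold changes are on that scale, which understates the change of low genes. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all 14668 genes tested, and the threshold was 0.05. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 24 lists. Camera with an estimated correlation and fry stood beside it. For genes with 1 to 3 reads in a group, the ratio was given with an exact (Clopper-Pearson) 95% interval, which covers counting error alone.

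The groups, the test, the 24 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The genes named were Senp7, the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 50 and no overlap between groups, up to 4 members of each list with the smallest adjusted p, and a fixed set of myosin, actin, titin, myogenic factor, atrophy and SENP genes with Flii. Predicted gene models and pseudogenes were left out of the largest changes. Other list members are named where a list is described, as chosen after their values were seen. Single-gene results of a few list members are not reported here.

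Alternatives were the replicate number as a block, DESeq2 1.42.0, limma-voom and edgeR 4.0.16 on the recovered reads, other scalings, filters and pseudocounts, a stricter threshold, a test against a fold of 1.2, and each library left out. For single genes, counts of settings and ranges over all settings leave out the stricter threshold and the test against a fold of 1.2. edgeR's quasi-likelihood test on the recovered reads called 3027 genes. Added after the data were seen were removal of the trend on GC content and gene length, edgeR with TMM, and 2 further gene lists (HIF targets and imprinted genes).

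On simulated data with 200 changed genes among 14507, the procedure called 74.6% of genes changed by 1.5-fold, 92.5% at 2-fold and 98.5% at 4-fold. It made 13 false calls, 6.84% of all calls. The changed genes were drawn from those with a control mean of at least 50. With no change simulated the procedure called 0 genes, and 7 of 200 random lists had an unadjusted camera p below 0.05. Every gene was simulated independently, so neither lists of correlated genes nor a library displaced in many genes were examined. Exon overlaps with other genes were read from the coordinates. Because the strand setting is unknown, reads of a gene and its antisense partner could not be assigned with certainty, and the myosin heavy chain genes share near-identical stretches.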

Results

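Transcript levels were measured by RNA-seq in C2C12 myotubes, 3 cultures treated with control siRNA and 3 with SENP7 siRNA. Each library held between 25223218 and 30865945 reads assigned to genes. The comparison between the 2 groups asked which transcripts depend on SENP7 in these muscle cells, with sarcomere genes as the subject named by the study. Values are normalized read counts as mean ± SD with n = 3 libraries per group, and adjusted p-values are from limma with Benjamini-Hochberg adjustment unless another test is named.

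Senp7, the siRNA target, lies on chromosome 16 from 56048338 to 56190012 on the plus strand (ENSMUSG00000052917.15, GRCm38). Its normalized counts were 556.4, 616.4 and 648.8 in the control libraries and 275, 279.2 and 346.7 in the SENP7 siRNA libraries. The mean fell 2.03-fold, from 607.2 ± 46.9 to 300.3 ± 40.2, a log2 fold change of -1.02 ± 0.11 (SE, adjusted p = 0.000428). Among transcripts of the other SENP proteases, Senp3 (-0.05), Senp5 (-0.11), Senp6 (0.05) and Senp8 (0.07) did not pass the test, nor did Senp1, whose log2 fold change of -0.03 turned to 0.04 without SENP7 replicate 3. Senp2 was lower by a small step (-0.19 ± 0.06, adjusted p = 0.042), a call that was lost in 9 alternative settings, with adjusted p of 0.0814, 0.11, 0.16 and 0.173 without control replicates 1 or 2 or SENP7 replicates 1 or 2 and a range of 0.0304 to 0.173 over all settings.

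SENP7 siRNA changed 3062 of 14668 tested genes (20.9%), of which 1492 rose and 1570 fell, and 672 changed by more than 2-fold (416 higher, 256 lower). When only genes with a mean of at least 50 were tested, 347 changed by more than 2-fold (196 higher, 151 lower). The largest rises included Cdkn1c, a cyclin-dependent kinase inhibitor, and Fmo1, a flavin-containing monooxygenase, and the largest falls included Gja5, a gap junction connexin, and Cyp11a1, the enzyme that starts steroid hormone synthesis. Cdkn1c (chromosome 7, 143458339 to 143461050) went from 161.4 ± 37.4 to 1730 ± 92.5, and Fmo1 from 185.7 ± 38.9 to 1446 ± 56.3. Gja5 (chromosome 3, 96904693 to 97077416) went from 3455 ± 439 to 534.1 ± 42.8. The plot of counts per library shows these genes beside Senp7 and the myosins.

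**Figure D1:**
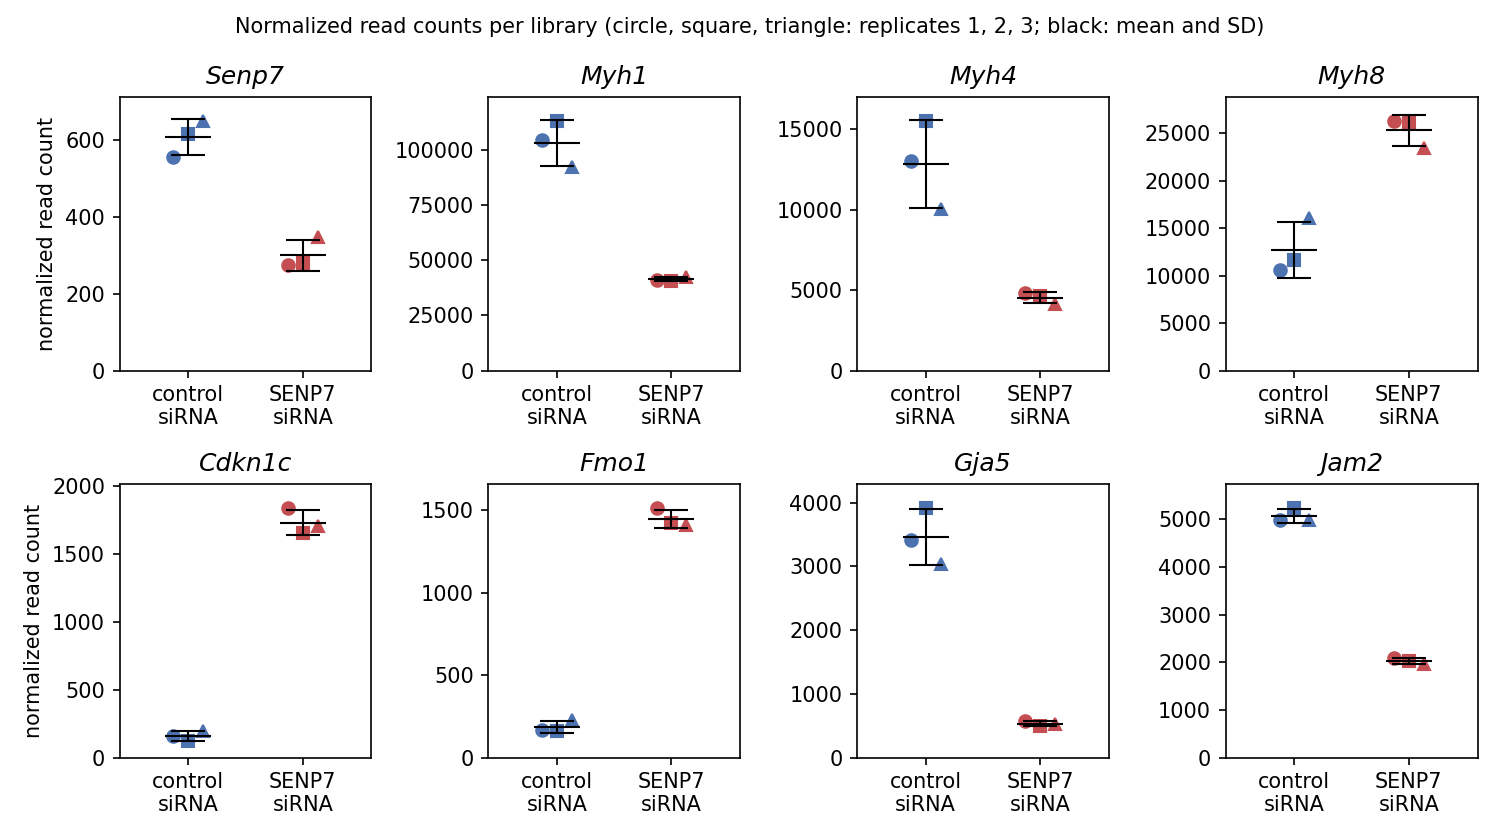
Normalized read count (y axis, from 0) of 8 genes in each control siRNA and SENP7 siRNA library, with circles, squares and triangles for replicates 1, 2 and 3 and black bars for mean and SD. In every panel the 3 libraries of one group lie apart from the 3 of the other, with Senp7 at 556.4 to 648.8 in controls and 275 to 346.7 after SENP7 siRNA.

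Epha8, an ephrin receptor, had 1 read over the 3 control libraries and 335 over the 3 SENP7 libraries, a ratio of 314 with an exact 95% counting interval of 55.9 to 12426. Eef1a2, the elongation factor 1A form of adult muscle and neurons, rose from 3.023 ± 2.51 to 129.4 ± 73.8, and the cell adhesion molecule Nrcam from 12.49 ± 3.65 to 372.6 ± 90.3. The sodium pump subunit Atp1b2 rose 10.3-fold. The kinase gene Nrk rose 8.52-fold, Tceal6 8.8-fold, the transcription factor Plagl1 7.69-fold and the collagen gene Col24a1 by 2.88 on the log2 scale. Among the falls, Cyp11a1 went from 166.9 ± 97.3 to 5.769 ± 1.75, Gdf6, a bone morphogenetic protein family member, from 208.8 ± 44.1 to 20.8 ± 5.94, and Car9, a carbonic anhydrase induced by low oxygen, from 1134 ± 682 to 107.1 ± 28. Prr9 fell 10-fold and the hypertrophic cartilage collagen Col10a1 fell 8.53-fold. Ighm, the immunoglobulin mu heavy chain, fell 6.61-fold, the mast cell protease Mcpt8 6.55-fold and the chemokine receptor Cxcr6 5.86-fold. Sprr1a fell 5.97-fold with an adjusted p of 0.0221, and leaving out any library except control replicate 3 ended that call, with adjusted p between 0.0569 and 0.106 (5.71e-06 to 0.206 over all settings). The call of Car9 was lost without a filter on low genes (adjusted p = 0.0759) and with the replicate number as a block (adjusted p = 0.11), with 7.4e-07 to 0.11 over all settings. Control replicate 3 lay far below control replicates 1 and 2 in several of these falls. Its counts were 57.39 against 199.6 and 243.6 for Cyp11a1 and 355 against 1426 and 1622 for Car9. For Mcpt8 they were 153.7 against 395.1 and 421.7. The same held for Prr9 (47.66 against 163.3 and 106.8) and Sprr1a (27.24 against 177.4 and 173.6). In Ighm (1048) and Col10a1 (126.5) control replicate 3 was not the lowest control.

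Of the changed genes, 3054 had no overlap between the 3 control and the 3 SENP7 values. Such separation held for 39.6% of all tested genes, where chance gives 10%. Control replicate 3 stood apart from control replicates 1 and 2, with a first principal component (64.4% of the variance) of -19.1 against -36.7 and -33.3, where the SENP7 libraries lay between 27.7 and 32.5. Without it 4702 genes changed, and 1633 changed without control replicate 2, 1660 without SENP7 replicate 1 and 1619 without SENP7 replicate 2. SENP7 replicates 1 and 2 were the closest pair, with a chi-square per gene of 1.7 against 7.26 to 36.9 in all other pairs of the same group. Sampling noise alone gives a value of 1, and a value above it does not show that the 2 libraries came from separate cultures. Both were kept because the submitters state that they are biological replicates.

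Among the thick and thin filament genes, the transcripts of fast adult myosin heavy chains fell and that of perinatal myosin rose. Myh1, the IIx myosin (chromosome 11, 67200052 to 67224575), fell 2.48-fold from 103400 ± 10400 to 41500 ± 951, and Myh4, the IIb myosin, fell 2.79-fold from 12840 ± 2740 to 4536 ± 358. Myh2, the IIa myosin, fell 1.63-fold, and whether reads shared with Myh1 lowered its count was not tested. Myh8, the perinatal myosin (chromosome 11, 67277124 to 67308634), rose from 12740 ± 2940 to 25300 ± 1600, a log2 fold change of 1.01 ± 0.14 (adjusted p = 0.00165). These 4 genes kept their direction and passed the test in every alternative setting run. The embryonic myosin Myh3 was at 179700 ± 23400 and 228200 ± 14700 and missed the threshold (log2 fold change 0.35, adjusted p = 0.0635), although it passed in 7 settings, among them without control replicate 3 (adjusted p = 0.000976, with 0.000976 to 0.221 over all settings). The slow myosin Myh7 was lower, with a log2 fold change of -0.88 ± 0.23 (adjusted p = 0.0272). Its count in control replicate 3 (12710) was far above those in control replicates 1 and 2 (6344 and 6891), and the call was lost in 7 settings, among them without control replicate 2 (adjusted p = 0.0571) and without SENP7 replicates 1, 2 or 3 (0.0611, 0.0816 and 0.11), with 0.00294 to 0.231 over all settings.

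The filament list as a whole moved both ways. Of 34 members, 6 rose, 8 fell and 20 did not pass (9 rose and 8 fell adjusted over the list alone), and camera found no direction (adjusted p = 0.539). The fast myosin-binding protein gene Mybpc2 rose from 1595 ± 175 to 3614 ± 214, and Tmod1, which caps thin filaments, from 2955 ± 292 to 5727 ± 158, with exons of Tstd2 on the opposite strand over 32.6% of its exon length. The major sarcomere transcripts Actc1 (log2 fold change 0.28 ± 0.14) and Ttn (0.22 ± 0.16) did not pass the test, and Acta1 did not either (0.16 ± 0.10), with a sign that turned to -0.03 under quantile normalization. Ttn and Actc1 each passed in 1 alternative setting. Flii, an actin-remodelling protein gene, was at 10680 ± 237 and 11690 ± 222 (log2 fold change 0.13, not passing in any setting). Falling members were 3 without control replicate 2 and 5 without SENP7 replicate 2 (8 with all libraries), and 10 rose and 10 fell without control replicate 3. The balance turned with the replicate number as a block (12 rose and 6 fell), with DESeq2 and under quantile normalization (10 and 8 each), without a filter on low genes (10 and 5), after removal of the trend on GC content and length (8 and 6) and without control replicate 2 (5 and 3) or SENP7 replicate 3 (7 and 6).

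Z-disc and M-band genes mostly rose where they changed. Of 35 members, 12 rose and 3 fell (the same counts adjusted over the list alone), with a camera adjusted p of 0.242. Ankrd2, a stretch-responsive ankyrin repeat protein, rose from 997.3 ± 193 to 2835 ± 348, and the intermediate filament gene Synm from 79.2 ± 18.4 to 318.8 ± 49.6. Smpx rose by 0.54 on the log2 scale, whereas Ankrd1 fell from 25740 ± 664 to 16990 ± 202. Rising members were 7 without SENP7 replicate 1, and falling members were 7 without control replicate 3 and 1 without control replicate 2. In the list of sarcomere chaperones and assembly factors, 3 of 23 members rose and 2 fell (6 and 4 adjusted over the list alone, camera adjusted p = 0.539). The myosin chaperone Unc45b (log2 fold change 0.67) and Klhl41 (0.41) rose, and the small heat shock protein Hspb7 (-0.96) and the caveola protein Cavin4 (-0.59) fell. Without control replicate 3, 4 members of that list rose and 5 fell.

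Among myogenic regulators, more genes rose than fell. Of 24 members, 8 rose, 2 fell and 14 did not pass (10 and 2 adjusted over the list alone), with a median log2 fold change of 0.27 and a camera adjusted p of 0.00228, which became adjusted p = 0.514 with an estimated correlation. Myf6, the late myogenic factor MRF4, rose from 82.88 ± 7.23 to 299.3 ± 35.7, and Myod1 from 4168 ± 248 to 5550 ± 88.8. Cdkn1c belongs to this list too. Myog was at 20790 ± 2190 and 25280 ± 2530 and missed the threshold (log2 fold change 0.28), although it passed in 6 settings. Without control replicate 3, 13 members rose.

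In the list of calcium handling and excitation-contraction coupling, rising members outnumbered falling ones. Of 28 members, 11 rose, 3 fell and 14 did not pass (12 and 3 adjusted over the list alone), with a median log2 fold change of 0.15 and a camera adjusted p of 0.0094, which became adjusted p = 0.713 with an estimated correlation. The calcium sensor gene Stim1 rose from 1863 ± 166 to 3328 ± 153, Stac3, a partner of the voltage sensor, by 0.60 on the log2 scale, and Mrln, which encodes a micropeptide inhibitor of the calcium pump, from 145.1 ± 15.6 to 337.7 ± 49.5. Sln, which encodes another inhibitor of that pump, had 2 reads in the control and 88 in the SENP7 libraries, a ratio of 41.2 (exact 95% counting interval 11.1 to 346). The store calcium buffer gene Casq1 fell (-1.05 ± 0.14). The falling members were 2 without control replicate 1, and 1 without control replicate 2 or without any 1 SENP7 library.

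Among 16 neuromuscular junction genes, 5 rose and 0 fell, also adjusted over the list alone, and camera missed the threshold (adjusted p = 0.0573). Ky rose from 36.01 ± 4.12 to 149.8 ± 27.7, and Chrne, the adult acetylcholine receptor subunit, from 137.4 ± 15.4 to 230.1 ± 33.1. The rising members were 2 without control replicate 2, SENP7 replicate 1 or SENP7 replicate 3, and 3 without control replicate 1. In the myoblast fusion list, 5 of 23 members rose and 6 fell (7 and 9 adjusted over the list alone, camera adjusted p = 0.539). The adhesion molecule gene Jam2 fell from 5058 ± 144 to 2024 ± 64.6 while its relative Jam3 rose from 615.3 ± 42.4 to 978 ± 46.7, and Cd9 fell by 0.48 on the log2 scale. The rising members of this list were 3 without any 1 SENP7 library. In the dystrophin complex and sarcolemma list, 5 of 25 members rose and 6 fell (6 and 10 adjusted over the list alone, camera adjusted p = 0.539). Dmd, the dystrophin gene, fell 2.71-fold and the muscle caveolin gene Cav3 fell 2.26-fold, whereas the syntrophin gene Sntb1 rose from 1639 ± 172 to 3508 ± 204. Popdc3 fell by 0.30 on the log2 scale. Rising members of the dystrophin list were 3 without control replicate 1, 2 without SENP7 replicate 3 and 1 without control replicate 2, SENP7 replicate 1 or SENP7 replicate 2, and the falling ones were 3 without SENP7 replicate 2.

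Of 45 oxidative phosphorylation genes, 21 rose, 0 fell and 24 did not pass (26 and 0 adjusted over the list alone), with a median log2 fold change of 0.23 and a camera adjusted p of 1.28e-07, which became adjusted p = 0.872 with an estimated correlation. Cox7a1, the heart and muscle form of a cytochrome oxidase subunit, rose from 105.1 ± 5.37 to 269 ± 25.6, and Ndufb10 (0.43), Uqcrc2 (0.38) and Sdha (0.35) rose by less on the log2 scale. Of 10 mitochondrially encoded mRNAs, 5 rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 0.000436), and their test gave adjusted p = 0.713 with an estimated correlation. mt-Nd5 rose from 101100 ± 3910 to 143500 ± 1930, and mt-Nd2 from 57150 ± 624 to 80180 ± 1480. Mitochondrial mRNAs made up 2.54%, 2.51% and 2.41% of the control libraries and 3.29%, 3.32% and 3.25% of the SENP7 libraries, and ribosomal RNA genes 0.232%, 0.21% and 0.229% of the control libraries and 0.306% of each SENP7 library. In the oxidative phosphorylation list, control replicate 3 lay 0.20 below the mean of control replicates 1 and 2 on the log2 scale. The rising members of that list were 11 without control replicate 2, SENP7 replicate 1 or SENP7 replicate 2, and the rising mitochondrial mRNAs were 3 without any of these.

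Glycolysis genes moved both ways. Of 24 members, 5 rose and 10 fell (6 and 13 adjusted over the list alone), and camera found no single direction (adjusted p = 0.283). The rising genes were Slc2a4, the insulin-responsive glucose transporter, from 24.08 ± 5.67 to 124.1 ± 14.2, Pygm, the muscle glycogen phosphorylase, from 5037 ± 714 to 10560 ± 334, the muscle phosphoglycerate mutase Pgam2 from 2832 ± 446 to 5802 ± 386, the phosphorylase kinase subunit gene Phkg1, and Ldhb. The falling genes included the widely expressed transporter Slc2a1 (-1.01 ± 0.23), Pgk1 (-0.86 ± 0.21), Aldoc (-1.87 ± 0.38) and Pkm (-0.67 ± 0.15). Control replicate 3 lay 0.40 below control replicates 1 and 2 in the mean of this list, at 11.49, below the SENP7 libraries (11.57 to 11.63). Without it 15 members fell, whereas 6 fell without control replicate 1, 2 without control replicate 2, and 4, 3 and 5 without SENP7 replicates 1, 2 and 3.

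**Figure D2:**
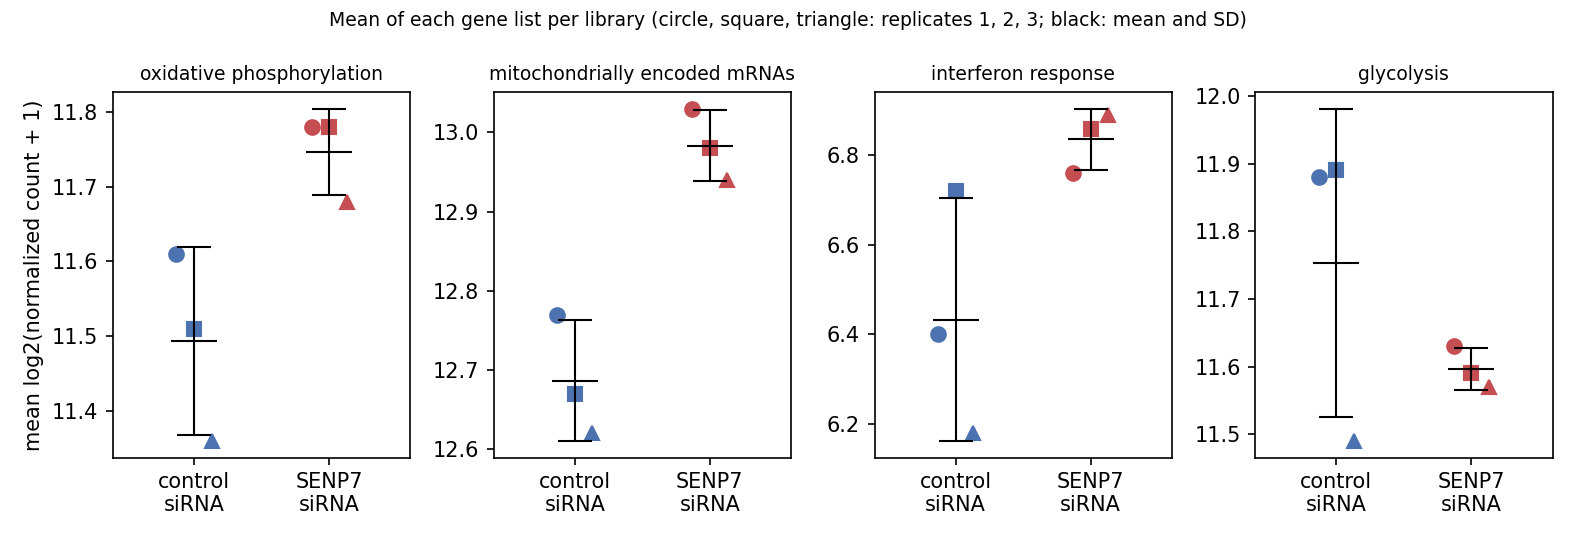
Mean log2(normalized count + 1) (y axis, not starting at 0) of 4 gene lists in each library, with circles, squares and triangles for replicates 1, 2 and 3 and black bars for mean and SD. Oxidative phosphorylation means were 11.36 to 11.61 in controls and 11.68 to 11.78 after SENP7 siRNA, while in glycolysis control replicate 3 (11.49) lay below the SENP7 libraries (11.57 to 11.63).

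Interferon response genes rose where they changed. Of 24 members, 6 rose and 0 fell (7 and 0 adjusted over the list alone), with a camera adjusted p of 0.000916, which became adjusted p = 0.713 with an estimated correlation. Mx2, of an antiviral GTPase family but annotated as a polymorphic pseudogene, rose from 19.39 ± 3.5 to 60.71 ± 2.7. Ifi35 rose from 516.9 ± 28.6 to 743.2 ± 32.2 and Xaf1 from 324 ± 45.1 to 467.6 ± 7.64. Gbp2 rose from 72.08 ± 14.2 to 123.7 ± 7.01, a call that was lost without SENP7 replicate 2 (adjusted p = 0.0504, with 0.00218 to 0.0504 over all settings). The list holds 34 genes, and those not tested, among them Rsad2, Mx1 and Usp18, did not meet the filter on counts. The mean of the tested members was 6.40, 6.72 and 6.18 on the log2 scale in control replicates 1, 2 and 3. In SENP7 replicates 1, 2 and 3 it was 6.76, 6.86 and 6.89, so control replicate 2 lay close to SENP7 replicate 1. Control replicate 3 lay 0.38 below the mean of control replicates 1 and 2. Without control replicate 2, 9 members rose, and without SENP7 replicate 2, 4 did.

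The muscle atrophy list showed no direction, with 4 of 28 members rising and 3 falling, also adjusted over the list alone (camera adjusted p = 0.778). The atrophy ubiquitin ligases Fbxo32 (log2 fold change -0.09) and Trim63 (-0.16) did not pass, although Trim63 passed in 1 setting. Gadd45a fell from 9360 ± 1260 to 5652 ± 35.6 and Gabarapl1 by 0.29 on the log2 scale, and Fbxo31 rose from 847.6 ± 48.6 to 1192 ± 29. Mstn, the growth inhibitor myostatin, had 1 read in the control and 39 in the SENP7 libraries, a ratio of 36.5 (exact 95% counting interval 6.18 to 1479). Without control replicate 3, 6 members rose and 6 fell, and 2 rose without control replicate 2, SENP7 replicate 1 or SENP7 replicate 2.

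Few SUMO pathway genes passed the test. Of 26 members, 1 rose and 2 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.778), namely Sumo2 (0.25), Pias2 (-0.21) and Senp2, and the calls of Sumo2 and Pias2 were each lost in 7 settings with adjusted p up to 0.133 and 0.125. Of 23 genes of heterochromatin and HP1 partners, 1 rose and 1 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.778). Morc3 rose from 1963 ± 102 to 2754 ± 71.6, whereas the small fall of Smarca4 (-0.19) was lost in 9 settings (adjusted p up to 0.166). Without control replicate 3, 4 of these 23 genes rose.

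Of 36 cell cycle genes, 0 rose and 1 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.17). It was Rrm2 (-0.29), whose call was lost in 4 settings (adjusted p up to 0.0806). In that list 1 rose and 2 fell without control replicate 3, 0 and 3 without control replicate 2, 2 and 0 without SENP7 replicate 3, and 0 and 0 without control replicate 1, SENP7 replicate 1 or SENP7 replicate 2. Of 24 p53 targets, 0 rose and 5 fell (1 and 5 adjusted over the list alone, camera adjusted p = 0.283), among them Ccng1 (-0.38). Cdkn1a fell by 0.48 on the log2 scale, a call lost without control replicate 2 or SENP7 replicates 2 or 3 (adjusted p = 0.0696, 0.0643 and 0.0707, with 0.000633 to 0.0707 over all settings). Falling p53 targets were 1 without control replicate 2 or SENP7 replicate 2, 2 without SENP7 replicate 3 and 3 without SENP7 replicate 1, whereas 3 rose and 7 fell without control replicate 3. Of 24 cholesterol synthesis genes, 1 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.539), with Sqle at -0.24 and Dhcr7 at 0.25, calls that were each lost in 3 settings. Of these 24 genes, 2 rose and 4 fell without control replicate 3, 2 and 1 without SENP7 replicate 3, and 0 and 0 without control replicate 2, SENP7 replicate 1 or SENP7 replicate 2. In the unfolded protein and integrated stress response list, 4 of 29 members rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.803). Fgf21, a stress-induced hormone of muscle and liver, rose from 603.9 ± 119 to 1207 ± 153. The rising members of that list were 1 without control replicate 2, SENP7 replicate 1 or SENP7 replicate 2 and 2 without control replicate 1, with 0 falling in each of these, whereas 4 rose and 3 fell without control replicate 3.

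Extracellular matrix genes moved both ways. Of 34 members, 6 rose and 7 fell (8 and 8 adjusted over the list alone, camera adjusted p = 0.778). Thbs2 fell from 6555 ± 72.2 to 3412 ± 146, Timp1 from 5526 ± 991 to 2877 ± 35.1 and Tnc from 29320 ± 6850 to 13990 ± 1700, whereas the basement membrane collagen Col4a1 rose from 10680 ± 775 to 14950 ± 622. The call of Tnc was lost without a filter on low genes (adjusted p = 0.065, with 2.81e-10 to 0.065 over all settings). Without control replicate 3, 10 members rose and 12 fell.

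Markers of other cell states and types were examined too. In the list of undifferentiated myoblasts and reserve cells, 7 of 24 members rose and 6 fell (8 and 6 adjusted over the list alone, camera adjusted p = 0.873). The cyclin gene Ccnd1 fell from 1282 ± 69.4 to 564.6 ± 4.35 and the growth factor antagonist gene Spry1 by 0.64 on the log2 scale, while Notch1 rose from 1749 ± 112 to 2988 ± 89.9 and Fgfr4 from 650.2 ± 16.3 to 1211 ± 194. The rising members were 3 without control replicate 2. Exons of LTO1 on the opposite strand cover 23.4% of the exon length of Ccnd1. Of 11 osteoblast markers, 1 rose and 3 fell (1 and 4 adjusted over the list alone, camera adjusted p = 0.157). Spp1, which encodes osteopontin, fell from 22610 ± 5190 to 8748 ± 1510, and Dlx3 fell 1.85-fold, whereas Phex rose from 17.9 ± 1.87 to 45.24 ± 1.44. Of 11 adipocyte markers, 3 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.539), with lipoprotein lipase (Lpl) rising from 86.89 ± 24.2 to 269 ± 38.4, Plin4 from 57.09 ± 5.55 to 158.8 ± 25.2, and Adipor2 and Cd36 falling by 0.82 and 0.40 on the log2 scale. Of 5 tested endothelial and macrophage markers, 2 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.283). Tek (from 5.445 ± 0.868 to 14.25 ± 2.53) and Itgam (from 6.87 ± 2.11 to 14.82 ± 1.06) rose at low counts, and Cd14 fell from 126 ± 11.5 to 90.3 ± 12.8, calls that were lost in 4, 8 and 11 settings.

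**Figure D3:**
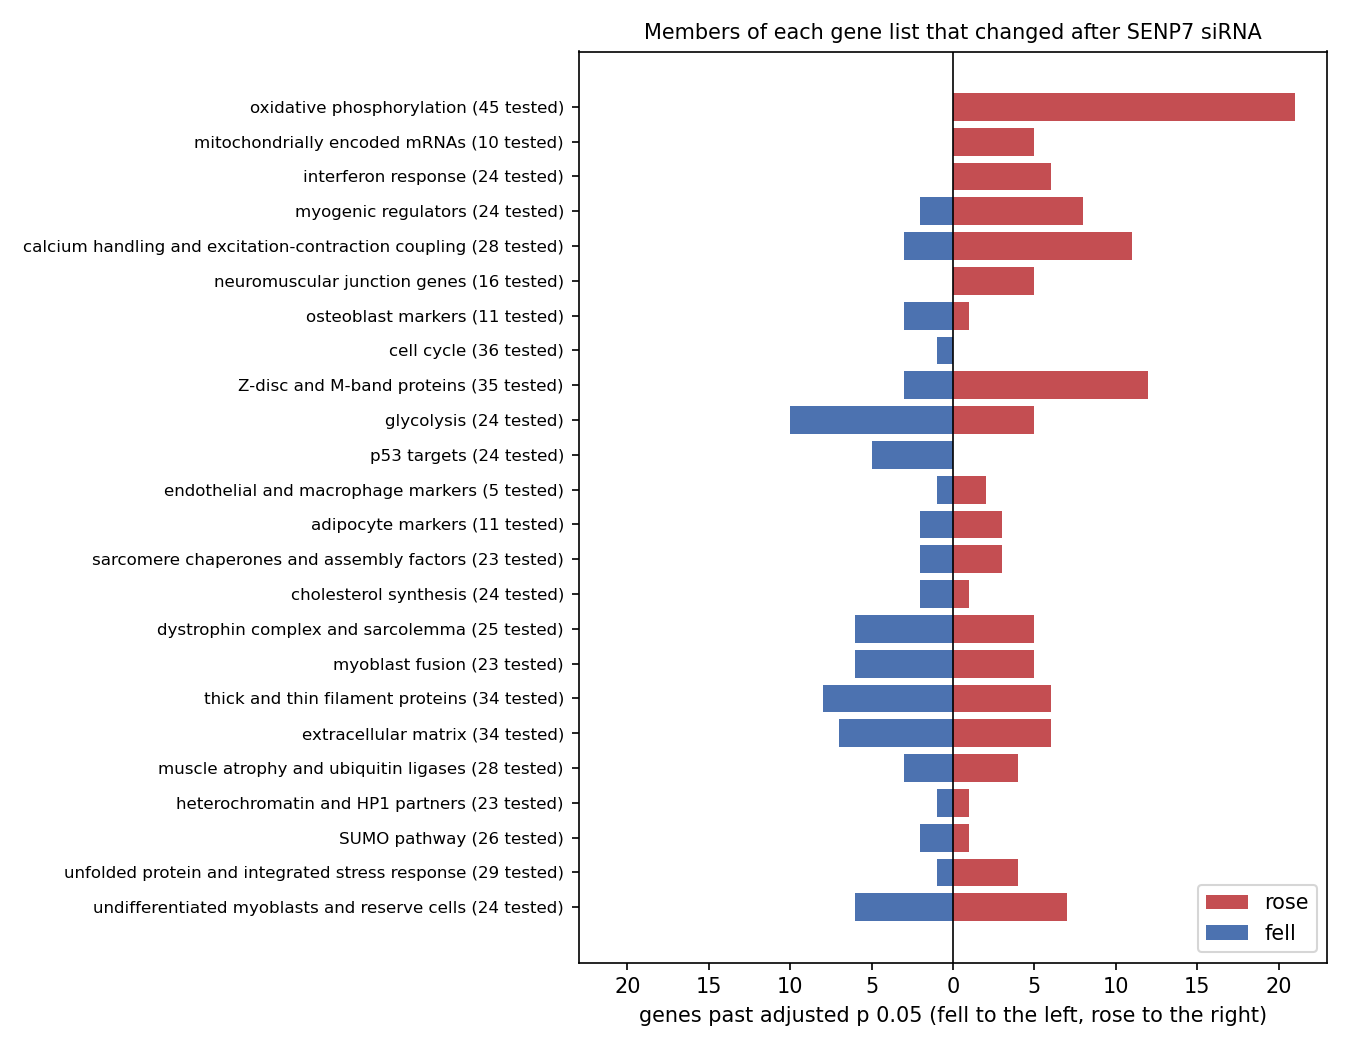
Number of genes (x axis) of each of the 24 gene lists that passed the limma test at an adjusted p of 0.05, with falling genes to the left of 0 and rising genes to the right, and the number tested beside each list name. Oxidative phosphorylation had 21 rising and 0 falling genes, whereas thick and thin filament proteins had 6 rising and 8 falling.

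In the authors' deposited table, 2545 genes passed an adjusted p of 0.05, of which 1223 were higher and 1322 lower after SENP7 siRNA. Of the genes called by limma, 1178 were higher and 1280 lower in both, 0 went in opposite directions, and 604 did not pass in the authors' deposited table. The authors' deposited table gives a log2 fold change of -0.94 for Senp7, 3.13 for Cdkn1c and -2.54 for Gja5. DESeq2 on the recovered reads called 2955 genes, of which 2540 were shared with the authors' deposited table in the same direction.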

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

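Among the alternative settings, those chosen only after the data were seen were edgeR with TMM on the recovered reads and removal of the trend on GC content and length. The other settings were planned. Of 122 named genes, 109 passed the threshold. All 109 kept their direction in every setting compared, and 84 of them passed in every one. The stricter threshold and the test against a fold of 1.2 were not among these settings, nor were settings whose filter left a gene out. The 2 signs that turned belonged to genes that did not pass, Acta1 (-0.03 under quantile normalization) and Senp1 (0.04 without SENP7 replicate 3, and -0.07 to 0.04 over the omissions of 1 library), and the cause was not tested. Leaving out 1 library at a time gave 1619 to 4702 changed genes, 805 to 2289 higher and 754 to 2413 lower, with the highest total without control replicate 3 and the lowest without SENP7 replicate 2. Of the 4702 genes, 2979 were among the 3062 called with all libraries. A test against a fold of 1.2 called 841 genes, 470 higher and 371 lower, and an adjusted p under 0.01 left 1398, with 718 higher and 680 lower, both by construction stricter. With a mean of at least 50, 11937 genes were tested and 2666 of them changed. Of these, 347 changed over 2-fold, 196 higher and 151 lower, against 672 with the main filter. Many of the 672 therefore lay in genes with a mean below 50. With an estimated correlation between genes, camera gave an adjusted p of 0.514 for myogenic regulators. It gave 0.713 for calcium handling, interferon response and mitochondrially encoded mRNAs, and 0.872 for oxidative phosphorylation. None of the 5 lists called at the preset correlation passed. The estimated correlation of myogenic regulators was 0.00671, below the preset 0.01, so correlation did not cause that loss. With the correlation estimated, camera also takes its degrees of freedom from the 6 libraries, which leaves little power. For calcium handling the estimated correlation was 0.126 and for mitochondrially encoded mRNAs 0.246. It was 0.277 for interferon response and 0.732 for oxidative phosphorylation. All of these lay above the preset 0.01, so the preset p-values of these lists allow for less correlation than was estimated. How much of each loss came from low power was not tested. Fry gave 0.0607 for interferon response and 0.0656 for oxidative phosphorylation, and the other 3 passed it. Some lists that camera did not call passed fry as well. Rising ones were endothelial and macrophage markers (fry adjusted p = 0.00606), neuromuscular junction genes (0.0227) and adipocyte markers (0.0319). Falling ones were osteoblast markers (fry adjusted p = 0.00606) and myoblast fusion (0.0319). With DESeq2, lists were counted but not tested. With the replicate number as a block, 4175 genes were called, of which 3028 were shared. The plan did not read the numbers as pairs, because the submitters state no pairing. Same-numbered libraries deviated together with correlations of 0.13, 0.06 and 0.25. Control and SENP7 replicates 3 correlated best with each other, while not every library did so with its own number. Effects shared by same-numbered libraries therefore stay open. Depth limits genes near the floor of 10 normalized counts, where 1 read is worth 0.887 to 1.11.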

Other observations

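The HIF target and imprinted gene lists, and the tests of scaling, culture state, low counts, a silent allele and delayed maturation, were chosen only after the results they bear on were seen. Many genes that hypoxia-inducible factors are known to induce fell. Of 42 tested members, 0 rose, 27 fell and 15 did not pass, with a median log2 fold change of -0.62, and 0 of 10000 random lists matched on expression had a median as low. The random lists, here and for the imprinted genes, were drawn gene by gene and do not reflect variation between libraries. The estimated correlation between the HIF targets was 0.734. The camera adjusted p was 1.67e-10 over the 2 added lists, which became adjusted p = 0.238 with an estimated correlation. The glycogen branching enzyme gene Gbe1 fell by 2.50, the prolyl hydroxylase Egln3 by 2.11, Bnip3 by 1.21, Slc16a3, the lactate exporter, by 1.08, Pdk1 by 0.91 and Vegfa by 0.61 on the log2 scale. Ldha (-0.54, adjusted p = 0.071), Adm (-0.16) and Hmox1 (0.15) did not pass.

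Among imprinted genes, which are known for expression from 1 parental allele in at least some tissues, more rose than fell. Of 31 tested members, 13 rose, 1 fell and 17 did not pass, with a median log2 fold change of 0.22, and 0 of 10000 random lists had a median as high. The camera adjusted p was 0.000237, which became adjusted p = 0.124 with an estimated correlation. Beside Cdkn1c and Plagl1, Mest rose from 924.8 to 4190 normalized counts, Peg10 from 545.7 to 1706, Igf2 from 68.06 to 166, Grb10 from 21.35 to 56.02, Igf2r from 4947 to 7180 and its antisense RNA Airn from 70.18 to 170.7. Gnas fell (-0.43), and H19 (-0.42) did not pass. Without control replicate 3, 15 members rose and 4 fell, and 0 fell without control replicate 1 or 2. Members expressed from the maternal allele (Cdkn1c, Igf2r) and from the paternal allele (Mest, Peg10, Plagl1) were both among the rising ones. Exons of Copg2 on the opposite strand cover 23.1% of the exon length of Mest, and exons of Mest cover 17.8% of that of Copg2. Whether reads of Mest were counted in the smaller rise of Copg2 was not tested. An overlapping gene model covers 62.8% of the exon length of Igf2.

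The fall of HIF targets was not removed by other processing. At least 25 members fell under each of 7 other scalings or tools. In these, the median log2 fold change over all tested genes ran from -0.00642 (quantile normalization) to 0.0217 (library size alone). Such shifts are small beside the list median of -0.62, so the count shows only that the choice among these scalings mattered little. The list median was -0.61 after the trend on GC content and length was removed. Control replicate 3, however, had a mean of 10.62 on the log2 scale, against 11.32 and 11.33 in control replicates 1 and 2 and 10.28 to 10.34 in the SENP7 libraries, so that it lay 68.8% of the way from its group to the other. Without it 37 members fell, and 11 to 15 fell without any other 1 library. A culture state such as oxygen, cell density or medium that varied between wells may therefore account for part of the difference, and it stays open beside an effect of SENP7.

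Low counts were not the source of most of these calls, as 12 of the 13 rising imprinted genes had a mean of at least 50. All 13 kept over 50% of their change after the trend on GC content and length was removed. If the silent allele had been switched on at unchanged output per allele, no gene could rise over 2-fold. Of the 13, 4 (Cdkn1c, Mest, Plagl1 and Peg10) had 95% intervals wholly above 1 on the log2 scale and the other 9 did not, with Grb10 (1.38), Igf2 (1.33), Airn (1.29) and Dcn (1.05) estimated above 1 and Igf2r (0.55), Zim1 (0.53), Peg13 (0.39), Copg2 (0.37) and Dhcr7 (0.25) below it. This explanation stays open for those of the 9 that have a silent allele in these cells, and which of them do was not examined. Allele-specific reads, which would decide it, were not analysed here.

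Reads that fall on identical exon stretches shared with other genes moving the same way could pass on a share of a change. If reads covered each transcript evenly, this share came to 0.918% for Myh1, 0.193% for Myh8 and 34.8% for Myh4. Stretches that match with a few differences were not counted. Shared reads thus stay open for part of the fall of Myh4. This share was not computed for Myh2, which has 755 of its 7063 exon stretches in common with Myh1. Mean counts over all libraries were 72450 for Myh1 and 3041 for Myh2, so shared reads stay open for the fall of Myh2 too. Without any 1 library, Myh1, Myh4 and Myh8 stayed past the threshold, with a highest adjusted p of 0.0161. A delay in maturation of the cultures would be expected to lower the genes of calcium handling and excitation-contraction coupling too. Their rising members outnumbered the falling ones by 8. That count was known before this prediction was written, and Casq1 of the same list fell, so it cannot decide whether maturation was delayed. An siRNA acting on other transcripts was not tested because the design held 1 siRNA against SENP7.

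The real division of the 6 libraries gave 3062 changed genes and the highest of the other splits gave 0, where 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. Every other split held libraries of both treatments in each of its groups, which widens the spread within groups. Their 0 calls are therefore no measure of what chance alone would give. The transcriptional coactivator gene Ppargc1a went from 55.44, 80.1 and 118.7 normalized counts in the control libraries to 223.6, 203.3 and 300.3 in the SENP7 libraries. Mamstr, a MEF2 coactivator gene, was at 107.8, 103.5 and 77.82 in the control and at 505.7, 515.6 and 487.9 in the SENP7 libraries. Hif1a transcripts did not pass (log2 fold change -0.13 ± 0.06). These 3 genes were singled out after their values were seen.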
